A study of Homo sapiens with 8 samples.

How the data were processed

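Messenger RNA was measured in AGS, an established cell line derived from a human gastric adenocarcinoma, on 8 Affymetrix expression arrays. Per the labels, 4 arrays carried RNA of control cells and 4 carried RNA of cells kept for 72 hours with podofilox at 3.4 nM. Podofilox, also called podophyllotoxin, is a plant compound that binds tubulin and blocks the assembly of microtubules. Total RNA was isolated with TRIzol and converted to biotin-labelled cRNA, per the labels, so each array has 1 colour and no question of the direction of a ratio arises. The labels do not say whether the control cells received the solvent of the drug, nor whether the replicates of a group were separate cultures. The p-values therefore measure the spread between these arrays, which may be technical.

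The deposited table holds log2 expression values, 1 per probe set and array, which the authors made with RMA (robust multi-array average, which corrects the background, normalizes the arrays by quantiles and summarises the probes of a set), per the submitters' processing notes. The software, version and options of that step are not given in the sources used here. The log2 scale was read from the values, which ran from 2.64 to 15.0 over all arrays. Read as natural logs, the brightest value would come to 3348660, whereas a 16-bit scanner reaches only 16 on the log2 scale. The deposited median was 6.43, 6.41, 6.45 and 6.44 on control arrays 1 to 4, and 6.44, 6.43, 6.39 and 6.44 on podofilox arrays 1 to 4. The values keep the level of each probe set and show no centring per gene. The table carries no detection calls, so dim probe sets were not marked as absent, and the number of arrays limits the precision.

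Of the 49395 probe sets, 102 were manufacturer controls, 44988 were assigned to 1 gene by the platform annotation, 1832 to several genes, and 2473 were unnamed here. The Entrez identifiers of 44961 single-gene probe sets were found in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. No coordinates are given, since no genome build is named for the platform annotation. Each gene was represented by its single-gene probe set with the highest mean over the 8 arrays, which left 18132 genes. Of these, 11734 had more than 1 probe set, and 4640 were represented by a probe set of the _x_at or _s_at kind, which can bind more than 1 transcript. Probe sets of several genes and unnamed ones stayed out of the main tests. Some members of the gene lists lacked a single-gene probe set and were not analysed here.

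Podofilox and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 8 arrays, no intensity filter). A gene is said to have risen or fallen where its two-sided Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Errors of log2 fold changes are limma's moderated standard errors (SE), and intervals cover 95%. A set of 20 gene lists was fixed from textbook knowledge and tested with camera at its preset correlation between genes of 0.01, adjusted over the 20 lists. The lists cover alpha and beta tubulin genes, G2 and mitosis, DNA replication, p53 targets, MYC targets, autophagy, lysosome, the BCL2 family, amino acid and endoplasmic reticulum stress, cholesterol synthesis, SRF and YAP targets, NF-kB targets, interferon-stimulated genes, hypoxia and glycolysis, epithelial-mesenchymal transition, polyadenylated histone genes, gastric epithelial genes, and markers of fibroblasts, immune cells and endothelial cells. Control probe sets were compared with exact two-sided permutation tests over the 70 arrangements of the arrays. These tests, and the permutation test of replication against mitosis genes, take the arrays as freely exchangeable. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

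The genes named in the text follow a fixed rule. It takes the 10 largest rises and 10 largest falls among genes past the test whose groups do not overlap and whose mean is at least 5 in a group, MYC and ATG10, which the study is known to have followed up, and up to 4 members of each list with the smallest p. Other genes, and 13 gene families picked by symbol, were chosen after their values were seen. The lists, the rule, the tests of genes and of lists, and most alternatives were fixed before the data were examined. The alternatives fixed then were a filter on dim genes, quantile normalization or median centring once more, an intensity trend with robust estimation, array weights, the replicate number as a block, a plain t-test per gene, all probe sets or their mean per gene, each array left out in turn, and for lists an estimated correlation and fry.

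Further alternatives were added after seeing the data. Most were added because the 18S control probe sets of arrays numbered 1 and 2 resembled each other within each group, as did those of arrays 3 and 4. The poly-A spike-ins paired in this way on podofilox arrays, but control array 1 (7.32) lay nearer to 3 and 4 (7.31 each) than to 2 (7.41). The alternatives added for the pairs are a batch term for the numbers, each batch alone, each pair averaged and each pair as a random block. The removal of _x_at and _s_at probe sets was added because such probe sets can bind other transcripts. The procedure was tested on simulated data with the 18132 genes and 4 against 4 arrays, 200 of the genes being changed in each of 5 runs. It recovered 37.9% of genes changed by 0.25 on the log2 scale, 88.1% of those changed by 0.5 and 99.7% of those changed by 1, and 4.64% of its calls were false. The simulated noise was normal and independent between genes and arrays, so it held no pairs of arrays. These rates need not carry over to the data, where 3810 genes were called.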

Results

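AGS gastric cancer cells grown with 3.4 nM podofilox for 72 hours were compared with control cells on 4 arrays each, and 18132 genes were measured. The comparison asks which mRNAs change in these cells when they are kept with a drug that binds tubulin. All values are on the log2 scale of the deposited table, and a difference is podofilox minus control. Across genes, which are not independent replicates, arrays of the same group correlated at 0.997 to 0.999 and arrays of different groups at 0.995 to 0.997. The first principal component held 47.1% of the variance and separated the 4 podofilox arrays from the 4 control arrays.

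The cells with podofilox had more mRNA for the cancer-testis antigen LEMD1 (2.80-fold), the hypoxia-responsive gene ANKRD37 (2.57-fold), the chemokine interleukin-8, CXCL8 (2.35-fold), tissue plasminogen activator, PLAT (2.33-fold), and the gastric trefoil peptide TFF1 (2.11-fold). They had less mRNA for the nuclear receptor ESRRG (1.997-fold lower), the bone morphogenetic protein receptor BMPR2 (1.94-fold lower) and ID3, an inhibitor of helix-loop-helix transcription factors (1.71-fold lower). Of 26 DNA replication genes 23 fell, and of 25 MYC target genes 18 fell, whereas 11 of 20 genes of amino acid and endoplasmic reticulum stress and 8 of 17 NF-kB targets rose. MYC itself did not pass the test, with a mean of 11.49 ± 0.08 (SD, n = 4) in control cells and 11.39 ± 0.07 (SD, n = 4) with podofilox. ATG10, a conjugating enzyme of autophagy, fell from 6.68 ± 0.02 to 6.07 ± 0.16 (SD, n = 4 each) on a probe set of the _x_at kind, while its other probe set did not pass the test (-0.17).

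By limma, 3810 genes (21.01%) changed, 1550 of them upward and 2260 downward. Most changes were small. The median change of a called gene was 1.19-fold, 134 genes changed by at least 1.5-fold (78 rose and 56 fell), and 6 changed by at least 2-fold. All 6 of these rose on the brightest probe set, although OSMR, 1 of the 6, was lower on its 4 other probe sets. A fall of at least 2-fold was seen in 0 genes by limma, and also in 0 genes at an unadjusted p under 0.05 and without limma's moderation of the variances, where each gene is read from its brightest probe set. ESRRG lay just short of it on that probe set, and 3 of its other probe sets fell further (-1.26, -1.16 and -1.11). The 4 podofilox values lay all above or all below the 4 control values for 4747 genes (26.2%), where chance alone gives 2.86%.

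**Figure D1:**
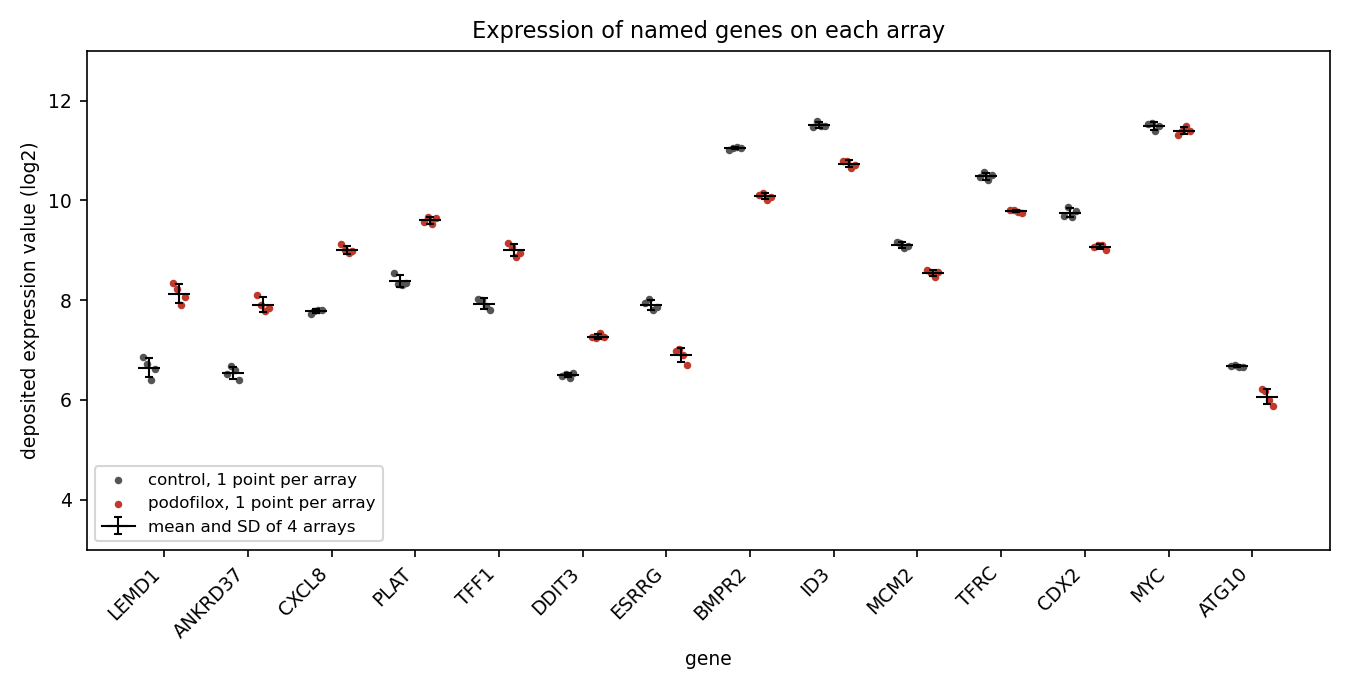
Deposited log2 expression value (vertical axis) of 14 named genes (horizontal axis), 1 point per array, with the mean and SD of 4 control (grey) and 4 podofilox (red) arrays. LEMD1, ANKRD37, CXCL8, PLAT, TFF1 and DDIT3 are higher on every podofilox array, ESRRG, BMPR2, ID3, MCM2, TFRC, CDX2 and ATG10 are lower, and the MYC points overlap (11.49 against 11.39).

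Among the 10 largest rises, LEMD1 went from 6.65 ± 0.19 to 8.13 ± 0.19 (SD, n = 4 each), a difference of 1.49 (SE 0.11, adjusted p = 3.36e-05). ANKRD37 rose by 1.36 (SE 0.08, adjusted p = 9.31e-06), CXCL8 by 1.23 (SE 0.05, adjusted p = 2.96e-06) and PLAT by 1.22 (SE 0.06, adjusted p = 7.35e-06). TFF1 rose by 1.08 (SE 0.07, adjusted p = 1.87e-05). PLAUR, the urokinase receptor, and the membrane protein TM4SF1 rose by 0.93 and 0.92. The membrane progestin receptor PAQR5 rose by 0.96. OSMR, a receptor subunit for oncostatin M, rose by 1.14 (SE 0.05) on its brightest probe set but fell on its 4 other probe sets, with differences from -0.54 to -0.28, and its mean over probe sets fell by 0.14. HNMT, which methylates histamine, rose by 0.94 on its representative, with a further probe set rising by 0.26 and another changing by -0.29, and its call ended with the mean of its probe sets (0.10, adjusted p = 0.0783). In each of the 10 genes all 4 podofilox arrays lay above all 4 control arrays, which the rule for naming them required. Within arrays numbered 1 and 2 these rises ran from 0.85 (TM4SF1) to 1.49 (LEMD1), and within arrays 3 and 4 from 0.87 (PLAUR) to 1.48 (LEMD1).

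Of the 10 largest falls, BMPR2 went from 11.05 ± 0.02 to 10.09 ± 0.06 (SD, n = 4 each), a difference of -0.96 (SE 0.04, adjusted p = 4.25e-06), while its other probe sets were at -0.88, past the test, and -0.13, not past it. ESRRG changed by -0.998 (SE 0.08, adjusted p = 3.51e-05). ID3, a target of bone morphogenetic protein signalling, changed by -0.78 (SE 0.05, adjusted p = 1.5e-05). APOA2, an apolipoprotein of high-density lipoprotein, changed by -0.87, and the tyrosine kinase SYK by -0.76. The zinc finger genes ZNF112 and ZSCAN5A changed by -0.89 and -0.82. CLRN3, PRSS35 and the F-box gene FBXO30 changed by -0.90, -0.86 and -0.78. All 4 podofilox arrays lay below all 4 control arrays for each of these genes, again as the naming rule required. Within arrays 1 and 2 the falls ran from -0.98 (ESRRG) to -0.74 (ID3), and within arrays 3 and 4 from -1.02 (ESRRG) to -0.74 (ZSCAN5A).

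The genes that duplicate DNA fell almost throughout. Of 26 measured genes of DNA replication and S phase, 23 fell and 0 rose (25 and 0 when adjusted over the list alone), and the list was lower by camera (adjusted p = 5.78e-15, and adjusted p = 0.0115 with an estimated correlation). MCM2, a subunit of the replicative helicase, changed by -0.56 (SE 0.05, adjusted p = 6.84e-05), GINS2 by -0.55 (SE 0.06), and POLE2, a subunit of DNA polymerase epsilon, by -0.52 (SE 0.05). UHRF1, which maintains DNA methylation at replication, changed by -0.52 (SE 0.04). RRM1 (-0.13), RRM2 (-0.10) and ORC1 (-0.17) did not pass the test. By contrast, of 27 measured genes of G2 and mitosis, 4 fell and 1 rose, the same counts as when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.827). CENPF and CENPE, which encode kinetochore proteins, changed by -0.35 (SE 0.04) and -0.22 (SE 0.05), and HMMR by -0.24 (SE 0.04), NEK2 rose by 0.16, a call that ended on leaving out any 1 of 5 arrays (adjusted p up to 0.0917), while CCNB1 (-0.10), CDK1 (0.11), PLK1 (-0.04) and TOP2A (0.03) did not pass the test. The mean change of the replication genes was lower than that of the mitosis genes (difference -0.30, SE 0.02, two-sided exact permutation p = 0.0286, the smallest that 70 arrangements can give). This comparison uses the same arrays and lists as camera, so it is not independent of the camera results.

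MYC targets, a list of genes for ribosome building, nucleotide synthesis and growth, were lower as well, with 18 of 25 falling and 0 rising over all genes tested and over the list alone (camera adjusted p = 4.37e-10, and adjusted p = 0.0115 with an estimated correlation). The list was fixed knowing that the study followed MYC, so its direction is not independent of what the study saw. TFRC, the transferrin receptor, changed by -0.71 (SE 0.05, adjusted p = 1.74e-05). The nucleolar genes NOP56, NOP58 and NOP16 changed by -0.58 (SE 0.05), -0.35 (SE 0.04) and -0.37 (SE 0.05). MYC differed by -0.10 (SE 0.05, 95% interval -0.22 to 0.02, adjusted p = 0.246). Its difference was -0.19 within arrays 1 and 2 and -0.0037 within arrays 3 and 4.

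The list of amino acid and endoplasmic reticulum stress was higher, with 11 of 20 genes rising and 0 falling, or 12 and 0 when adjusted over the list alone (camera adjusted p = 7.75e-10, and adjusted p = 0.00825 with an estimated correlation). DDIT4, an inhibitor of the growth kinase mTORC1, rose by 0.92 (SE 0.05, adjusted p = 7.44e-06), and DDIT3, the stress transcription factor CHOP, by 0.78 (SE 0.04, adjusted p = 7.44e-06). HERPUD1, which acts in degradation at the endoplasmic reticulum, rose by 0.66 (SE 0.04), and ASNS, asparagine synthetase, by 0.52 (SE 0.05). ATF4 (0.08) and TRIB3 (0.07) did not pass the test. NF-kB targets were higher too, with 8 of 17 rising and 0 falling, or 10 and 1 when adjusted over the list alone (camera adjusted p = 3.57e-05, and adjusted p = 0.0428 with an estimated correlation). Besides CXCL8, the feedback inhibitor TNFAIP3 rose by 0.61 (SE 0.09, with 0.38 within arrays 1 and 2 and 0.84 within arrays 3 and 4), the cytokine LIF by 0.36 (SE 0.06) and the chemokine CXCL1 by 0.38 (SE 0.07). The call of CXCL1 ended without _x_at and _s_at probe sets (0.19, adjusted p = 0.0782).

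p53 targets went both ways, with 10 of 23 rising and 3 falling, the same over the list alone, and the list was higher on balance (camera adjusted p = 0.0013, and adjusted p = 0.0428 with an estimated correlation). GDF15, a secreted stress factor, rose by 0.79 (SE 0.05), GADD45A by 0.55 (SE 0.04), the cell death gene BBC3 by 0.53 (SE 0.05) and CDKN1A, the cell cycle inhibitor p21, by 0.45 (SE 0.05). TP53I3 changed by -0.56 (SE 0.06), the repair gene XPC by -0.19 (SE 0.04), and MDM2, which marks p53 for degradation, by -0.18 (SE 0.04). Of 19 hypoxia and glycolysis genes, 7 rose and 1 fell, also over the list alone (camera adjusted p = 0.00281, but adjusted p = 0.241 with an estimated correlation). Besides ANKRD37, NDRG1 rose by 0.81 (SE 0.06) and hexokinase HK2 by 0.43 (SE 0.04), while PFKFB3, which makes an activator of glycolysis, changed by -0.52 (SE 0.05) on its representative and by -0.05 without _x_at and _s_at probe sets (adjusted p = 0.554). Of 7 polyadenylated histone genes, 2 rose and 0 fell, or 4 and 0 over the list alone (camera adjusted p = 0.0144, but adjusted p = 0.0925 with an estimated correlation). That list also lost its call with the mean of probe sets per gene (adjusted p = 0.281) and within arrays 3 and 4 (adjusted p = 0.0714). H2AJ and H2BC21 rose by 0.17 (SE 0.05) and 0.34 (SE 0.09), calls that ended on leaving out any 1 of 4 and any 1 of 6 arrays (adjusted p up to 0.0795 and 0.0691), and H2BC5 (0.24) and H2AC6 (0.20) did not pass the test.

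**Figure D2:**
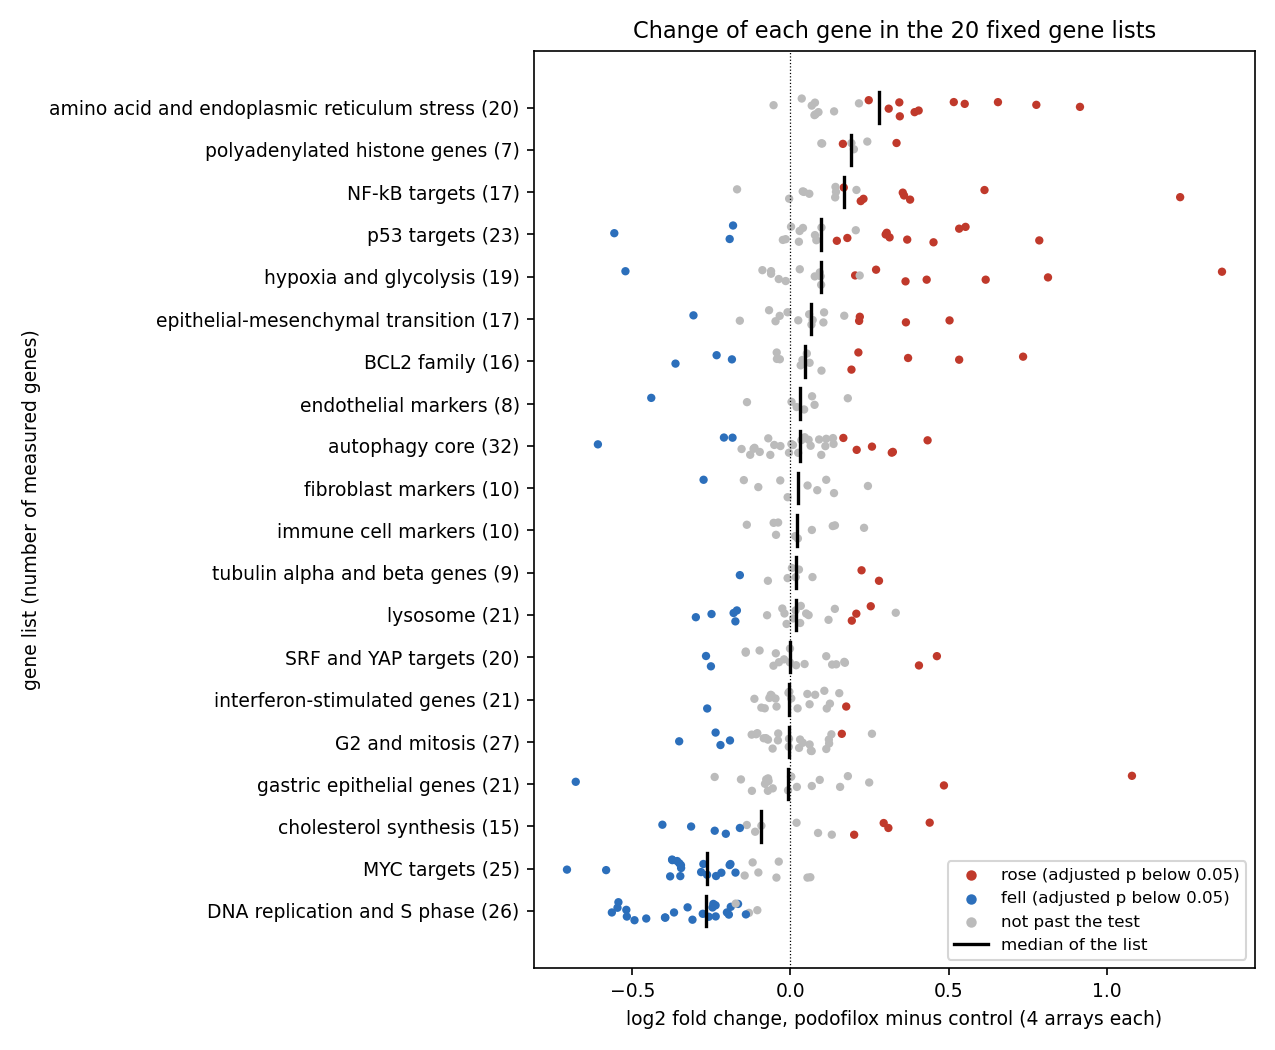
Log2 fold change of each measured gene (horizontal axis, podofilox minus control, 4 arrays each) in the 20 fixed gene lists (vertical axis, number of measured genes in brackets), with red points for genes that rose, blue for genes that fell, grey for genes not past the test, and a black bar at the median of each list. Blue points fill the lists of DNA replication (median -0.27) and MYC targets (median -0.26), and the list of amino acid and endoplasmic reticulum stress has the highest median (0.28).

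Autophagy genes did not shift as a list (camera adjusted p = 0.602). Of 32 genes, 6 rose and 3 fell, or 7 and 6 when adjusted over the list alone. GABARAPL1 and MAP1LC3B, whose proteins are joined to the autophagosome membrane, rose by 0.43 (SE 0.05) and 0.26 (SE 0.04), and WIPI1 by 0.32 (SE 0.04). ATG10 was the member that fell most (difference -0.61, SE 0.07, 95% interval -0.77 to -0.45, adjusted p = 0.000333), and all 4 podofilox arrays lay below all 4 control arrays. It is a gene the study chose on these samples, so its place among the fallen members is not independent evidence. Its difference was -0.50 within arrays 1 and 2 and -0.72 within arrays 3 and 4. This value comes from a probe set of the _x_at kind, which can bind other transcripts, and its other, dim probe set was at 4.29 ± 0.13 in control cells and 4.12 ± 0.04 with podofilox (SD, n = 4 each), a difference of -0.17 that did not pass the test (adjusted p = 0.0963 without _x_at and _s_at probe sets).

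The lysosome list did not shift (camera adjusted p = 0.938), with 3 of 21 genes rising and 5 falling, or 4 and 5 over the list alone. The cathepsin CTSB rose by 0.25 (SE 0.05) and the cholesterol transporter NPC1 by 0.21 (SE 0.05), while ATP6V0D1 and ATP6V1H, subunits of the proton pump, changed by -0.30 (SE 0.05) and -0.25 (SE 0.05). In the BCL2 family, which controls cell death, 5 of 16 genes rose and 3 fell, also over the list alone, with no shift of the list (camera adjusted p = 0.192). PMAIP1, which promotes cell death, rose by 0.74 (SE 0.04), as did BBC3, and MCL1, which opposes it, rose by 0.37 (SE 0.04). BOK changed by -0.36 (SE 0.06), a call that ended without _x_at and _s_at probe sets (-0.08, adjusted p = 0.406).

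The tubulin genes, which encode the target of the drug, did not shift as a list (camera adjusted p = 0.848), and of 9 measured members 2 rose and 1 fell, also over the list alone. TUBA4A rose by 0.28 (SE 0.06) and TUBB2A by 0.22 (SE 0.05). TUBB changed by -0.16 (SE 0.05, adjusted p = 0.0305), and its call ended on leaving out any 1 of 6 arrays, all except control replicate 2 and podofilox replicate 1 (adjusted p up to 0.0812). TUBB4B differed by -0.07 and did not pass the test.

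Cholesterol synthesis genes moved apart, with 4 of 15 rising and 5 falling, also over the list alone (camera adjusted p = 0.938). MSMO1, INSIG1 and HMGCS1 rose by 0.44 (SE 0.07), 0.31 (SE 0.06) and 0.29 (SE 0.04), while LSS, lanosterol synthase, changed by -0.40 (SE 0.06). Within arrays 3 and 4 the differences of MSMO1 and INSIG1 were larger (0.58 and 0.43) than within arrays 1 and 2 (0.30 and 0.19). Of 20 SRF and YAP targets, 2 rose and 2 fell, or 3 and 3 over the list alone (camera adjusted p = 0.938). TAGLN, a smooth muscle actin-binding protein, and the transcription factor FOSL1 rose by 0.41 (SE 0.05) and 0.46 (SE 0.09, with 0.70 within arrays 1 and 2 and 0.23 within arrays 3 and 4), while THBS1 and AXL changed by -0.27 (SE 0.05) and -0.25 (SE 0.06). The call of AXL ended with the mean of its probe sets (-0.08, adjusted p = 0.176). Of 21 interferon-stimulated genes, 1 rose and 1 fell, or 0 and 1 over the list alone (camera adjusted p = 0.938), and the chemokine CXCL10 changed by -0.26 (SE 0.06). IRF7 rose by 0.18, a call that ended on leaving out any 1 of 7 arrays, all except podofilox replicate 3 (adjusted p up to 0.0874), and OASL (0.15) and IRF9 (0.12) did not pass the test. Of 17 genes of epithelial-mesenchymal transition, 4 rose and 1 fell, also over the list alone (camera adjusted p = 0.162, but higher among genes above the median signal, at adjusted p = 0.0222). The tight junction gene CLDN4 rose by 0.50 (SE 0.04), and ITGA5 and MMP9 rose by 0.22 each. MMP9 was dim, at 4.65 in control cells and 4.87 with podofilox, which limits what can be read of its change. The mesenchymal filament gene VIM changed by -0.31 (SE 0.05). This list joins epithelial genes with mesenchymal ones, so a shift of the whole list would not show a transition. Of 21 gastric epithelial genes, 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.938). The gene that fell, CDX2, belongs to intestinal cells, so the list is mixed and its lack of a shift does not settle whether gastric genes changed. Besides TFF1, ANXA10 rose by 0.49 (SE 0.09), and CDX2, a transcription factor of intestinal cells, changed by -0.68 (SE 0.05, adjusted p = 4.28e-05), while SOX2 differed by -0.16 and did not pass the test on its representative, although another of its probe sets fell (-0.52, adjusted p = 0.00226).

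Markers of other cell types did not shift between the groups. Of 10 fibroblast markers 0 rose and 1 fell, of 10 immune cell markers 0 rose and 0 fell, and of 8 endothelial markers 0 rose and 1 fell, with the same counts over each list alone (camera adjusted p = 0.938, 0.742 and 0.938). PDGFRA changed by -0.27 (SE 0.05) on its brightest probe set and rose on a pair of dimmer ones, by 0.30 and 0.43, with 0.09 as the mean over its probe sets. CDH5, the cadherin of endothelial cells, was at 5.24 ± 0.28 and 4.80 ± 0.04 (SD, n = 4 each), and its call ended with the mean of its probe sets (-0.12, adjusted p = 0.350) and on leaving out podofilox replicate 2 or 3 (-0.43, adjusted p = 0.052 and 0.0506). For the SRF and YAP, interferon, gastric, fibroblast and endothelial lists, the median, the mean and the camera direction did not all have the same sign. Of the 20 lists, 7 shifted by camera, 5 of them also with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 9. It added the BCL2 family (adjusted p = 0.00649) and epithelial-mesenchymal transition (adjusted p = 0.000366). Each of these added lists holds genes of opposed roles, so its call gives no direction for cell death or for the transition. On 1 array of a group the values of HNMT, PRSS35, MAP1LC3B, BOK, AXL, IRF9, SOX2 and CDH5 stood apart from the other 3, and leaving out that array ended none of the calls of the 6 that had one, while it began a call of IRF9 (0.14, adjusted p = 0.0489).

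The manufacturer's control probe sets also differed between the groups. The signal for 18S ribosomal RNA was 12.74 ± 0.17 on control arrays and 12.22 ± 0.22 on podofilox arrays (SD, n = 4 each), a difference of -0.51 (two-sided exact permutation p = 0.0286). It was -0.86 within arrays 1 and 2 and -0.17 within arrays 3 and 4. The permutation takes the arrays as freely exchangeable, but the 18S values paired by number (SD of 0.028 within a pair of a group). Where the pairs count as units, only 3 of the 35 splits keep them whole, too few for a permutation p under 0.05. The same limit applies to the other control probe sets. Poly-A spike-ins, bacterial RNAs added to the sample before labelling, were higher with podofilox by 0.21 (exact permutation p = 0.0286), by 0.27 within arrays 1 and 2 and by 0.14 within arrays 3 and 4. The control probe sets of beta-actin and GAPDH were lower on every podofilox array, by small amounts (-0.05 and -0.04, exact permutation p = 0.0286 each). Hybridization spike-ins, added after labelling, differed by 0.00434 (exact permutation p = 1). The difference between 3' and 5' probe sets of GAPDH and beta-actin, a measure of RNA integrity, changed by -0.00483 (exact permutation p = 0.8). The called genes had the same direction in both pairs of replicate numbers in 3810 of 3810 cases, although a gene of opposite directions would seldom pass the test. Over all genes, the differences within arrays 1 and 2 and within arrays 3 and 4 correlated at 0.540, and over called genes at 0.889. By camera with its preset correlation, the replication list was lower within each pair (adjusted p = 3.04e-13 and 1.26e-09), as were MYC targets (1.7e-08 and 7.82e-07). The stress list (3.7e-07 and 1.54e-07) and NF-kB targets (7.96e-05 and 0.000444) were higher within each by the same test. These tests had 2 arrays per group, took the genes of a list as nearly independent, and were not run with an estimated correlation. On all 8 arrays that estimate gave camera adjusted p = 0.0115 for the replication list and 0.0428 for NF-kB targets. The p-values within pairs are therefore no measure of how well the shifts repeat.

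**Figure D3:**
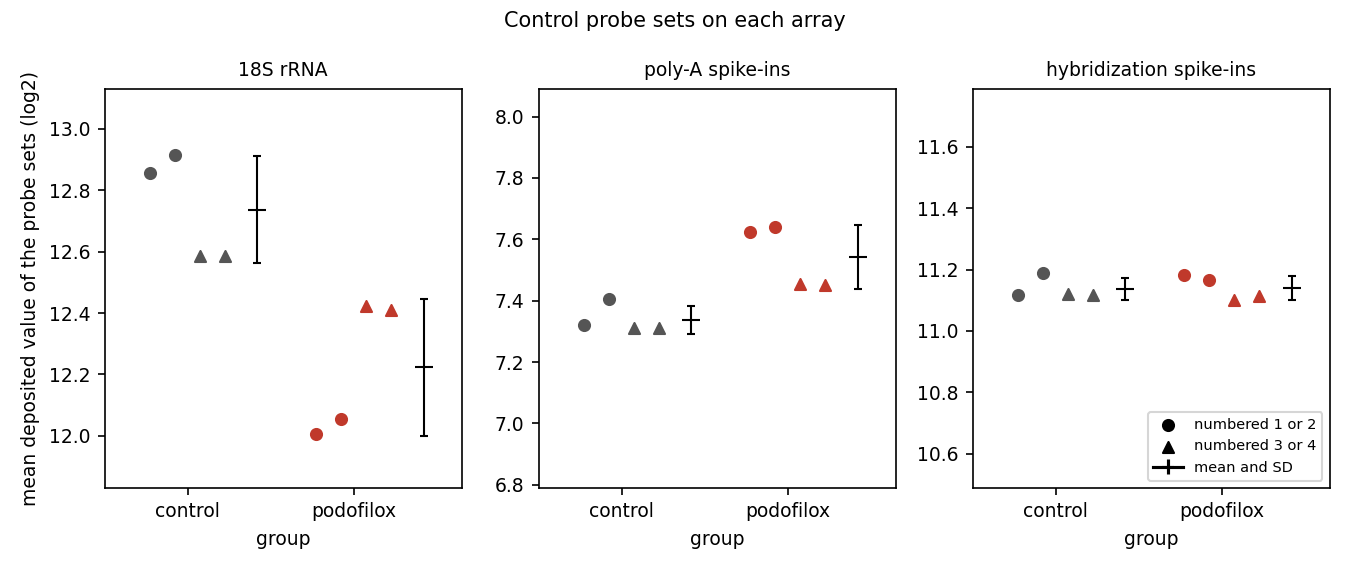
Mean deposited log2 value (vertical axis) of the 18S, poly-A spike-in and hybridization spike-in probe sets on each of 4 control (grey) and 4 podofilox (red) arrays, with circles for arrays numbered 1 or 2, triangles for those numbered 3 or 4, and the mean and SD of each group beside the points. The 18S signal is lower on every podofilox array (group means 12.74 and 12.22), the poly-A spike-ins are higher (7.34 and 7.54), and the hybridization spike-ins overlap.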

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

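The tests of the 18S signal against an array batch, against degraded RNA and against the gene changes were chosen only after the result was seen, on pairs of arrays found in the same data, while the removal of _x_at and _s_at probe sets was added after the data were seen with its outcome still unknown.

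The 18S control signal was lower on podofilox arrays by 0.51 (difference -0.51), and the poly-A spike-ins were higher by 0.21, although neither belongs to the measured genes. An effect common to both groups of arrays 1 and 2 cancels in the group difference by the design, whereas different handling of the groups within a pair of numbers stays open, and the differences within pairs (-0.86 and -0.171) do not test it. Degraded RNA is argued against by the 3' minus 5' difference of -0.00483 (interval -0.0337 to 0.024), where degradation was taken to need 0.3. Gene changes in proportion to the 18S control are argued against by the 1010 genes called within arrays 1 and 2 alone, a choice that favours larger changes there. Their median ratio to the change within arrays 3 and 4 was 1.12, against 5.01 for 18S. The interval of 1.08 to 1.16 comes from resampling genes, which are not independent, so it leaves out the spread between arrays. Proportion to the poly-A shift (0.27 within arrays 1 and 2, 0.14 within arrays 3 and 4) was not tested. A different amount of spike-in or sample RNA entering the labelling, or a changed share of ribosomal RNA in the treated cells, may be involved, and neither was tested.

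The DNA replication genes fell while the G2 and mitosis list did not shift. Brightness of the probe sets is argued against, since the median of -0.27 lay at percentile 0 of 10000 random lists matched on mean expression. The central 95% of those lists ran from -0.10 to 0.05. They hold unrelated genes, so this range leaves out the correlation between replication genes and may be too narrow. The random lists did not vary the normalization, but the median was -0.254 with quantile normalization once more and -0.249 with median centring. A fall of all cell-cycle genes alike is argued against by the difference of the list means, -0.297 (SE 0.02, two-sided exact permutation p = 0.0286, the smallest that 70 arrangements can give). That p takes the arrays as freely exchangeable. It comes from the same arrays and lists that camera had already set apart, so it is not independent evidence. The median of the mitosis list, -0.01, turned to 0.00 and 0.01 with quantile normalization and median centring, so it has no direction. As a hypothesis found on the same data, a smaller share of cells in S phase at 72 hours may be involved, but no measure of the cell cycle other than mRNA was analysed here.

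Of 1893 genes with at least 2 called probe sets, 103 (5.44%) had probe sets called in opposite directions. OSMR had 1.14 on its brightest probe set against -0.54 to -0.28 on 4 others, and TUBGCP3, a component of the gamma-tubulin complex named after its values were seen, had -0.73 to -0.36 on 4 probe sets against 0.52 on another. The count was reached in 1 of the 35 splits of the arrays, the real one, but the others called 0 probe sets and so had to give 0, which adds nothing. Probe sets of the _x_at and _s_at kind are argued against as the whole source, because 64 of the 103 genes (62.1%) kept opposed calls without them. Transcript isoforms that change in opposite directions could be a source, as could probe sets assigned to the wrong gene, and neither was tested, since probe sequences were not analysed here.

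Other ways of splitting the 8 arrays into 4 and 4 tested whether chance could give the counts. Chance is excluded for the 3810 changed genes only if the 8 arrays can be exchanged freely, since 1 of the 35 splits, the real one, gave as many, and the highest count of the others was 0. Where arrays 1 and 2, and 3 and 4, of a group count as pairs, only 3 of the 35 splits keep the pairs whole, too few for a share under 0.05, and 1399 genes changed with each pair averaged and 2856 with each pair as a random block. For the 6 genes changed at least 2-fold this was also 1 of 35 with 0 as the highest other, which is no separate evidence, since splits without called genes had to give 0. Chance is not excluded for the 7 shifted lists by this count, since 4 of the 35 splits gave 7 or more, and the highest of the others was 7. The 3 others exchange control replicate 2 for podofilox replicate 1, 2 or 4, so they keep 3 arrays of each group together. Splits with 2 arrays of each group on each side gave at most 2 lists, and the split of numbers 1 and 2 against 3 and 4 gave 0 genes and 0 lists.

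On some arrays a value stood far from the other 3 of its group, measured as the gap to the nearest value over the range of the group, and passed Dixon's critical value at 95%. This held for control replicate 2 in HNMT (0.895, at 7.81 against 7.64 to 7.65), IRF9 (0.868), the poly-A spike-ins (0.9) and the hybridization spike-ins (0.962). It held for control replicate 3 in AXL (0.929) and control replicate 4 in SOX2 (0.886). Podofilox replicate 1 stood apart in BOK (0.843, at 7.84 against 8.03 to 8.07) and HLA-DRA (0.902), podofilox replicate 3 in MAP1LC3B (0.838), and podofilox replicate 4 in PRSS35 (0.854, at 7.84 against 8.01 to 8.04) and CDH5 (0.998, at 4.85 against 4.78). These are 11 of 212 groups of values, and chance gives about 1 in 20, or 10.6.

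Probe sets outside the gene tests also differed between the groups. Of 1832 probe sets assigned to several genes, 298 changed (128 rose and 170 fell), and of 2473 probe sets unnamed here, 406 changed (169 rose and 237 fell).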

How the results depend on the processing

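The alternatives that use the pairs of arrays numbered 1 and 2 and 3 and 4, or leave out _x_at and _s_at probe sets, were added only after the data were seen. The count of changed genes stayed within 1.5 times of 3810 in 20 of 23 alternatives, from 2706 (without control replicate 4) to 5275 (array weights). It was 1010 within arrays 1 and 2, 2300 within arrays 3 and 4 and 1399 with each pair averaged, all with fewer samples, and 1390 of the last were among the 3810. Leaving out 1 array gave 2706 to 3590 genes, 6 to 7 genes changed at least 2-fold, 7 to 7 lists, MYC from -0.13 to -0.07 and ATG10 from -0.66 to -0.55. With control replicate 3, control replicate 4, podofilox replicate 1 or podofilox replicate 2 left out, 1 gene fell at least 2-fold, against 0 with all arrays. With all probe sets, 12 genes changed at least 2-fold (11 rose and 1 fell, from more probe sets per gene), and within arrays 3 and 4 it was 10, where the cause was not tested. ATG10 was at -0.17 (adjusted p = 0.0963) without _x_at and _s_at probe sets, which leaves its other probe set, and kept its call in the other 20 alternatives (adjusted p from 1.62e-05 to 0.0224). MYC stayed negative and short of the threshold in all 22 alternatives that gave it a value (adjusted p from 0.102 to 0.979). With the mean of probe sets per gene OSMR turned to -0.14 and PDGFRA to 0.0904, since their probe sets go both ways. Lists shifted numbered 5 (estimated correlation) to 9 (fry, which tests a list against no change and not against other genes). The polyadenylated histone list was untested without _x_at and _s_at probe sets and among genes above the median signal. Among the latter genes, the epithelial-mesenchymal transition list, which mixes epithelial and mesenchymal genes, was higher by camera (adjusted p = 0.0222). The share of called genes that fell was 59.3%, 54.3% with quantile normalization and 51.0% with median centring. With the replicate number as a block, 2741 genes changed, 2659 of them among the 3810, with 7 lists, MYC at -0.10 and ATG10 at -0.61. The numbers do not pair the samples, since deviations of arrays with the same number correlated at -0.24 to 0.09 and not every array correlated best with its own number. Of the 95 other named genes, 79 were called, and 69 of these kept the call in every alternative fixed beforehand and 44 in every alternative run. Over all alternatives, a call of a named gene ended 112 times and began 38 times. Leaving out 1 array ended the calls of TUBB, NEK2, IRF7, H2AJ, H2BC21 and CDH5, and began those of IRF9 and CD3E (each with either of 2 arrays left out), DCN, OASL and H2BC5 (1 array each). ATG10 gave no value among genes above the median signal, MYC and ATG10 gave none with all probe sets, and lists were not tested with all probe sets, with unmoderated variances or with pairs as a random block. Without detection calls, dim probe sets under 5, such as the other ATG10 probe set, limit what can be read of their changes.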

Other observations

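The 13 gene families here were chosen only after the result was seen, and so were the tests on them, which are camera with its preset correlation, adjusted over the 13 families. The inhibitors of DNA binding and the inhibitory SMAD genes, which are targets of bone morphogenetic protein signalling, were lower by this test. Of 6 measured, 5 fell and 0 rose (adjusted p = 0.000162, but adjusted p = 0.0907 with an estimated correlation), with ID3 at -0.78, SMAD7 at -0.56, ID2 at -0.49, ID1 at -0.41 and SMAD6 at -0.36. The median was -0.65 within arrays 1 and 2 and -0.34 within arrays 3 and 4. Of 23 dual-specificity phosphatases, which switch off MAP kinases among other targets, 6 rose and 1 fell (adjusted p = 0.0313, but adjusted p = 0.125 with an estimated correlation), with DUSP1 at 0.71, DUSP10 at 0.68 and DUSP6 at 0.37. Of 11 metallothioneins, which bind zinc and copper, 4 rose and 0 fell (adjusted p = 0.00362, but adjusted p = 0.125 with an estimated correlation), among them MT2A at 0.34. Of 47 keratins, 6 rose and 0 fell (adjusted p = 0.0354, but adjusted p = 0.398 with an estimated correlation), with KRT23 at 0.61 and KRT80 at 0.50. Of 57 RAB GTPases of vesicle traffic, 12 rose and 3 fell (adjusted p = 0.0354, but adjusted p = 0.125 with an estimated correlation), with RAB33B at 0.47 and RAB8B at 0.36.

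Several families that handle RNA and protein were lower by the same test. Of 52 DEAD- and DEAH-box RNA helicases, 24 fell and 1 rose (adjusted p = 6.4e-06, but adjusted p = 0.125 with an estimated correlation), with DHX9 at -0.59, DDX39A at -0.39 and DDX5 at -0.29. Of 74 mitochondrial ribosomal proteins, 22 fell and 1 rose (adjusted p = 7.57e-06, but adjusted p = 0.204 with an estimated correlation), whereas of 67 cytosolic ribosomal proteins 2 fell and 1 rose (adjusted p = 0.863), and whether these families differ was not tested. The median of the cytosolic family was 0.00 and turned to -0.01 with quantile normalization, and with the mean of probe sets per gene 5 fell and 3 rose. Of 22 nucleoporins, 10 fell and 0 rose (adjusted p = 0.000162, but adjusted p = 0.125 with an estimated correlation), with NUP62 at -0.40. Of 35 proteasome subunits, 13 fell and 2 rose (adjusted p = 0.000259, but adjusted p = 0.204 with an estimated correlation), with PSMC3 at -0.35 and PSMB9 at 0.37. Of 14 chaperonin subunits and tubulin cofactors, which fold tubulin, 8 fell and 0 rose (adjusted p = 0.00123, but adjusted p = 0.161 with an estimated correlation), with TBCE at -0.32, CCT7 at -0.28 and TBCB at -0.24. Of 531 zinc finger genes, 101 fell and 28 rose (adjusted p = 0.0338, but adjusted p = 0.166 with an estimated correlation). Of 38 kinesins, 8 fell and 2 rose and the family did not shift (adjusted p = 0.213), with 5 falling under median centring and 4 with the mean of probe sets per gene. The medians of the 12 families other than the cytosolic ribosomal proteins kept their sign with quantile normalization, median centring and the mean of probe sets per gene. They also kept it within each pair of arrays, but the families were picked on the values of these same arrays, so this is not independent evidence. Some medians within a pair were small, such as 0.01 for keratins within arrays 3 and 4. Calls within a pair could be few, as within arrays 1 and 2, where 0 RAB GTPases rose and 1 fell.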
